A study of Homo sapiens with 9 samples.

How the data were processed

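Total RNA was sequenced from DKO-1 cells, a human colorectal cancer cell line derived from DLD-1 that keeps only a mutant KRAS allele. The 9 libraries fell into 3 groups of 3. These were the parental line, a stable line expressing an shRNA against Alkbh5, and a stable line expressing an shRNA against Mettl3. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA, and ALKBH5 is an enzyme that removes it. Per the labels' protocols, cells were grown in supplemented DMEM with fetal bovine serum and RNA was taken with Trizol. Per the same protocols, libraries were made with a NextFlex small RNA kit with a modified step, size-selected on a Pippin Prep and sequenced on an Illumina NextSeq system. The labels do not give the shRNA vector or sequences, describe no control shRNA group, and do not say whether the 3 libraries of a group came from separate cultures.

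The deposited table held raw read counts per gene as whole numbers, with no normalization, per the file headers and the values. Per the submitters' processing notes, cutadapt, STAR and DESeq2 were used with the hg38 build. Versions, the counting tool, the annotation release and the strand setting are not given in the sources used here. Each gene came with an Ensembl identifier, a name, a biotype, a length and hg38 coordinates. Without a stated strand setting, antisense and overlapping genes cannot be separated with certainty, and genes with near-identical copies (histone genes, ribosomal protein genes with pseudogenes, RN7SL1) may share reads. Column names showed the group and a running number from 1 to 9 but not which labelled replicate a column was. Each column was therefore assigned to its group only, and libraries are named here by that running number: parental libraries 1 to 3, Alkbh5 libraries 4 to 6 and Mettl3 libraries 7 to 9.

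Total counts per library ranged from 14301995 to 32110972. Of 48811 genes in the table, 5304 had a count of 0 in all 9 libraries, and 48628 identifiers were matched to a current symbol, which was used where a list names a gene by it. No column outside these 9 libraries was used. Intervals and ratios from summed counts are at the 95% level and cover counting error only, since reads after PCR are not independent molecules.

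Counts were analysed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 19731 genes, and library sizes were scaled with TMM factors. A single fit over all 9 libraries with 1 coefficient per group and no covariates left 6 residual degrees of freedom. The common dispersion was 0.0581. The 3 comparisons were the Mettl3 libraries against the parental line, the Alkbh5 libraries against the parental line, and the Mettl3 against the Alkbh5 libraries. Each test was two-sided, p-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic, and levels are given as CPM, counts scaled to a common library total with the TMM factors. Adjusted p-values of genes below are from this edgeR test unless another tool is named.

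In simulated counts with 200 changed genes per run among 19731, drawn from the means, depths and dispersions of these libraries, 34% of 2-fold and 78.5% of 4-fold changes were recovered for the Mettl3 comparison with the parental line, and 5.06% of calls were false. For the Alkbh5 comparison the figures were 27.5%, 75% and 5.96%, and for the direct comparison 36.5%, 70.5% and 7.76%.

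Before the data were examined, 34 gene lists were fixed, covering the m6A machinery, RNA processing, signalling outputs, cell cycle, stress, metabolism, translation, epithelial and mesenchymal states, intestinal differentiation and markers of other cell types. The 33 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a comparison. Camera compares a list with all other genes. It was repeated with a correlation estimated from the data, and with fry. Fry's directional test asks whether the members move one way on balance and its mixed test asks whether they change in either direction.

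The genes named were also fixed by a rule. It took METTL3, ALKBH5 and the tested m6A writers, erasers and readers as a group. For each comparison with the parental line it took the 8 largest rises and falls among called genes with a mean of at least 10 CPM over the 6 libraries, no overlap between the groups' libraries and an approved-style symbol, which leaves out clone names, LOC and LINC numbers and pseudogene names. It added up to 3 called members of each list with the smallest p, the 5 largest each way in the direct comparison, and up to 5 genes each way called in both comparisons with the parental line. Genes outside this rule are stated as such where they appear, apart from those given as neighbours of MIR30A and WTAP.

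Shares of counts in gene classes were compared with exact two-sided permutation tests, which cannot go below p = 0.1 for 3 against 3 libraries. Both knockdown groups were compared with the same parental libraries. The overlap and correlation of the comparisons were therefore set beside 40 simulations of unchanged groups that share a parental group. Every library, the parental ones included, was drawn anew from a common mean per gene at these depths and dispersions. Genes were drawn separately, so the real parental libraries and the correlation between genes were not kept.

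Alternatives were other size factors (DESeq2 or upper quartile), no filter beyond 1 count, a filter of at least 1 CPM in at least 3 libraries, a fit of only the groups compared, no robust estimation, the DESeq2 1.42.0 Wald test, an adjusted p of 0.01, a log2 fold change of at least 1, and leaving out each library in turn. A correction for transcript GC content, a correction for GC content and gene length, and a fit without mitochondrial genes, RN7SL1 and WTAP were added after the data had been seen.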

Results

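The series measured gene expression in total RNA of DKO-1 colorectal cancer cells carrying an shRNA against the m6A methyltransferase gene Mettl3 or the m6A demethylase gene Alkbh5, with the parental line as the control and 3 libraries per group. Total counts were 14301995, 16345354 and 24883302 in parental libraries 1, 2 and 3, 15290488, 20586609 and 31254294 in Alkbh5 libraries 4, 5 and 6, and 28812776, 16252872 and 32110972 in Mettl3 libraries 7, 8 and 9. Since the labels do not say that the libraries of a group came from separate cultures, p-values measure only the spread between these libraries, which may be technical. No pair of libraries in a group agreed within sampling noise, with a chi-square per degree of freedom of at least 19, so all 9 were counted as separate samples.

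Across genes, the correlation of log CPM between libraries was 0.95 to 0.973 within the parental group, 0.975 to 0.983 within the Alkbh5 group and 0.971 to 0.979 within the Mettl3 group, and 0.951 to 0.985 between groups. Parental library 1 lay apart from the other 8 libraries on principal component 1, at -90.1, where the others lay between -16 and 36.3. This component held 26% of the variance. The same library held WTAP, a subunit of the m6A writer complex, at 4480 CPM, where the other 8 libraries ranged from 46.8 to 57.6 CPM. WTAP did not pass in either comparison with the parental line (log2 fold change -4.88, edgeR adjusted p = 0.276 for the Mettl3 libraries, and -4.85, adjusted p = 0.607 for the Alkbh5 libraries).

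Both targeted genes were examined in every library. ALKBH5 (chromosome 17, 18183078 to 18209954) was at 179, 131 and 129 CPM in parental libraries 1 to 3, at 50.6, 39.8 and 60.4 CPM in Alkbh5 libraries 4 to 6, and at 110, 126 and 115 CPM in Mettl3 libraries 7 to 9. It fell by 1.54 on the log2 scale in the Alkbh5 libraries against the parental line (SE 0.193, 95% interval -1.95 to -1.13, edgeR adjusted p = 0.00854). This call ended without Alkbh5 library 4 (log2 fold change -1.54, adjusted p = 0.105) or without Alkbh5 library 5 (-1.41, adjusted p = 0.085). METTL3 (chromosome 14, 21498133 to 21511342) was at 33.9, 17.4 and 37 CPM in the parental libraries, 32.4, 30.2 and 32.4 CPM in the Alkbh5 libraries and 28.9, 20.6 and 26.1 CPM in the Mettl3 libraries. No decrease of METTL3 mRNA was detectable in the libraries labelled Mettl3 (log2 fold change -0.22, SE 0.24, 95% interval -0.74 to 0.29, adjusted p = 0.668). Against the Alkbh5 libraries, all 3 of which lay above the Mettl3 libraries for METTL3, the log2 fold change was -0.33 (SE 0.24, adjusted p = 0.87). These libraries are therefore called the libraries labelled Mettl3, or Mettl3 libraries, and every direction given for them rests on the label alone.

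**Figure D1:**
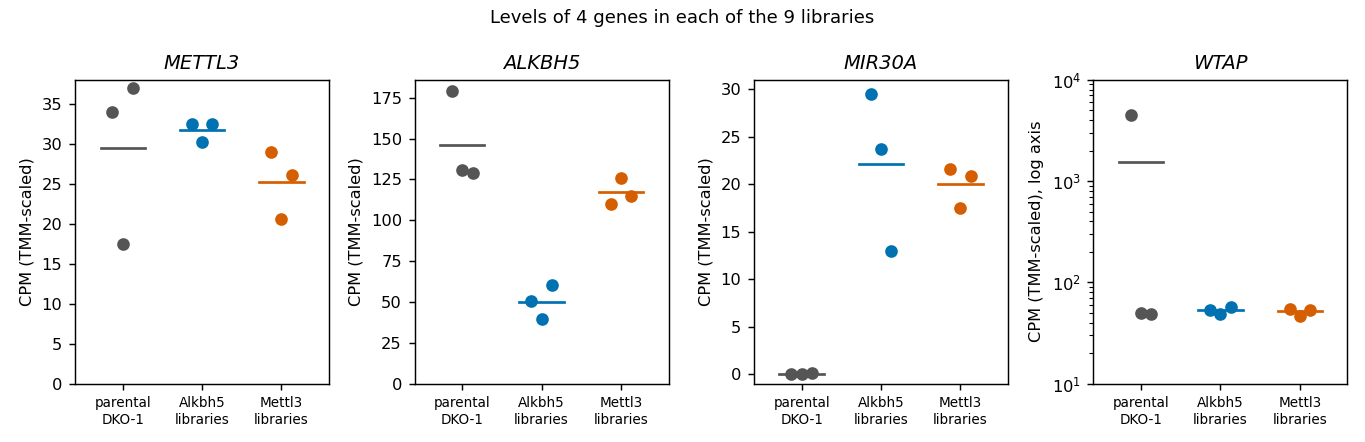
TMM-scaled CPM of METTL3, ALKBH5, MIR30A and WTAP in each library, 1 point per library and a line at each group's mean; the WTAP axis is logarithmic and the others are linear. ALKBH5 is lower in all 3 Alkbh5 libraries, the METTL3 levels of the Mettl3 and parental libraries overlap, MIR30A is near 0 in all 3 parental libraries, and WTAP is at 4480 CPM in parental library 1 alone.

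The comparison of the libraries labelled Mettl3 with the parental line asked which genes differ in the line made to deplete the m6A methyltransferase. Without a control shRNA group, both comparisons with the parental line also hold any effect of carrying an shRNA or of making the line. Of 28 tested intestinal differentiation genes, 6 were lower in the Mettl3 libraries, among them VIL1, which encodes the brush-border protein villin and went from 22 ± 1.37 to 5.14 ± 1.23 CPM (mean ± SD, n = 3 each), and CDX2, a transcription factor of intestinal identity, which went from 177 ± 39.8 to 57.2 ± 12 CPM. KRT20, a keratin of differentiated intestinal epithelium, was at 5.45 ± 3.87 CPM in the parental line and 0.129 ± 0.0622 CPM in the Mettl3 libraries. The WNT-responsive genes NOTUM, ASCL2 and APCDD1 were lower as well, while the stress-induced transcription factor genes ATF3, DDIT3 and JUN were each more than 2-fold higher. The microRNA gene MIR30A was at 20 ± 2.19 CPM in the Mettl3 libraries and 0.041 ± 0.071 CPM in the parental libraries.

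In this comparison 120 of 19731 genes passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 29 higher and 91 lower, and 101 of them changed at least 2-fold. Of the 120, 105 were protein-coding. An unadjusted p below 0.05 was reached by 3242 genes, where 987 would by chance. The counts of list members at this p given below are to be read against that share of the 19731 genes.

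The largest rises named by the rule, after MIR30A, were those of SLC7A11-AS1 (log2 fold change 1.60, SE 0.288) and SLC20A1 (1.30, SE 0.218). SLC7A11-AS1 is annotated antisense to the cystine transporter gene SLC7A11 and so is uncertain in counts of unknown strand. SLC20A1, a phosphate transporter gene, went from 193 ± 63.2 to 475 ± 46.5 CPM. UPP1, encoding uridine phosphorylase, rose by 1.28 (SE 0.247), CEP152, a centrosome gene, by 1.13 (SE 0.237) and NR1D1, a circadian repressor gene, by 1.08 (SE 0.231). Their edgeR adjusted p-values lay between 0.0174 for SLC20A1 and 0.0482 for NR1D1. The largest falls by the same rule were those of ATOH8 (-2.37, SE 0.304), a transcription factor gene, the choline transporter family gene SLC44A4 (-2.34, SE 0.238), KLHL4 (-2.14, SE 0.217), VIL1 (-2.11, SE 0.246), HR (-2.04, SE 0.313), CLIC3 (-1.91, SE 0.272), SIPA1 (-1.80, SE 0.251) and CDX2 (-1.63, SE 0.23). Adjusted p-values of these 8 genes ranged from 0.000283 for SLC44A4 and KLHL4 to 0.0083 for HR.

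Of the 28 tested intestinal differentiation genes, 6 fell and 0 rose in the edgeR test, with 10 lower and 1 higher at an unadjusted p below 0.05 and 7 lower in DESeq2. They were VIL1, CDX2, KRT20 (-5.24, SE 0.641, adjusted p = 0.00179), the secreted lectin gene REG4 (-3.08, SE 0.419, adjusted p = 0.00464) and, outside the naming rule and chosen after their values were seen, CEACAM5 (-1.97, adjusted p = 0.0275) and LGALS4 (-1.85, adjusted p = 0.0285). The CEACAM5 and LGALS4 calls each ended without parental library 2 or 3 or any 1 of the Mettl3 libraries, and so were kept in 4 of 9 fits (adjusted p from 0.00595 to 0.151 and from 0.00996 to 0.171). KRT20 rested on 4, 1 and 6 counts in Mettl3 libraries 7, 8 and 9. REG4, CEACAM5 and LGALS4 were low too. Their means were 7.69, 4.91 and 4.07 CPM in the parental and 0.973, 1.25 and 1.15 CPM in the Mettl3 libraries. Adjusted over the list alone, 8 members were lower and 1 higher. Other members did not pass, among them, outside the naming rule, HNF4A (-0.40, adjusted p = 0.275), KLF5 (-0.01, adjusted p = 0.991) and GATA6 (0.14, adjusted p = 0.661). The list median was -0.40 and camera called the list lower (adjusted p = 0.00029; adjusted p = 0.673 with an estimated correlation).

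**Figure D2:**
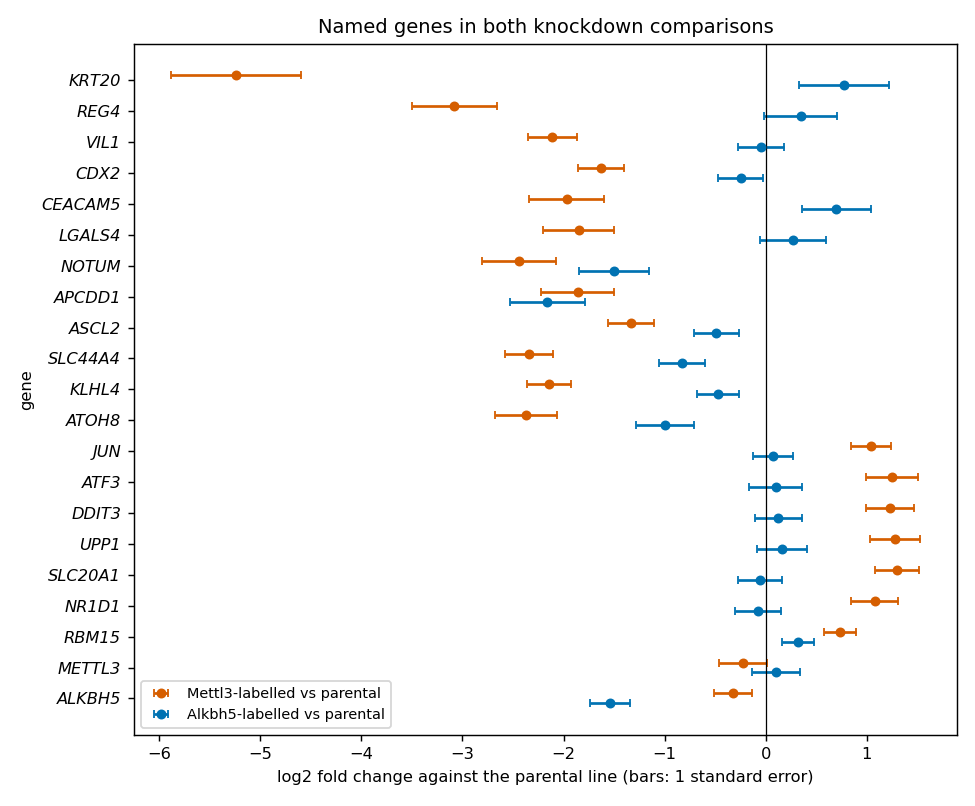
Log2 fold change against the parental line, with bars of 1 standard error, for 21 genes in the Mettl3-labelled and in the Alkbh5-labelled libraries (3 libraries each against 3). KRT20, REG4, VIL1 and CDX2 lie between -5.24 and -1.63 in the Mettl3 comparison and between -0.25 and 0.77 in the Alkbh5 comparison, while ALKBH5 lies at -1.54 in the Alkbh5 comparison.

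Among 27 tested WNT targets, 4 fell. They were the WNT-inactivating carboxylesterase gene NOTUM (-2.44, SE 0.368, adjusted p = 0.00754), the stem cell transcription factor gene ASCL2 (-1.33, SE 0.227, adjusted p = 0.0192), the WNT antagonist gene APCDD1 (-1.86, SE 0.362, adjusted p = 0.0344) and, chosen after its value was seen, AXIN2 (-1.13, adjusted p = 0.0437). With 1 library left out, NOTUM was kept in 7 of 9 fits (adjusted p up to 0.059), ASCL2 in 6 (up to 0.126), APCDD1 in 5 (up to 0.165) and AXIN2 in 4 (up to 0.204). All 4 calls ended without Mettl3 library 7 or 9, those of ASCL2, APCDD1 and AXIN2 also without parental library 3, that of APCDD1 without Mettl3 library 8, and that of AXIN2 without parental library 2 or Alkbh5 library 6. NOTUM and APCDD1 were low, at means of 3.24 and 5.17 CPM in the parental and 0.601 and 1.45 CPM in the Mettl3 libraries. Adjusted over the list alone, 7 WNT targets were lower and 1 was higher. Camera called the list lower with a median of -0.39 (adjusted p = 0.000158; adjusted p = 0.673 with an estimated correlation).

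Of 24 tested immediate early genes, ATF3 (1.25, SE 0.26, adjusted p = 0.0459) and JUN (1.04, SE 0.199, adjusted p = 0.0295) passed, both higher, and 4 were higher adjusted over the list alone. With 1 library left out, the ATF3 call was kept in 1 of 9 fits (adjusted p from 0.0496, without Alkbh5 library 5, to 0.226) and the JUN call in 5 (0.0191 to 0.18). Camera called the list higher (median 0.47, adjusted p = 0.003; adjusted p = 0.673 with an estimated correlation). DDIT3, the gene of the stress transcription factor CHOP, was the called member (1.23, SE 0.233, adjusted p = 0.0278) among 49 tested genes of the unfolded protein and ATF4 response. Of these 39 had a positive fold change and 3 were higher adjusted over the list alone (median 0.31, camera adjusted p = 0.00136; adjusted p = 0.684 with an estimated correlation). YAP targets, with 24 tested, had a median of 0.36 (camera adjusted p = 0.000561; adjusted p = 0.673 with an estimated correlation). Of them 0 were called over all genes by edgeR and 6 adjusted over the list alone, 10 reached an unadjusted p below 0.05 and DESeq2 called 5, all of these higher. MAPK and KRAS signalling output, with 35 tested, had a median of 0.27 (camera adjusted p = 0.00703; adjusted p = 0.684 with an estimated correlation). For this list edgeR called 0 members over all genes and 2 adjusted over the list alone, 7 were higher at an unadjusted p below 0.05, and DESeq2 called 4 higher. The 7 of 35 were a share near that of all tested genes (3242 of 19731).

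Of 50 tested G2/M cell cycle genes, 47 had a positive fold change and 12 were higher adjusted over the list alone (median 0.45, camera adjusted p = 2.16e-07; adjusted p = 0.673 with an estimated correlation). Over all genes edgeR called 0 of them, with 20 at an unadjusted p below 0.05, and DESeq2 called 4. Ribosomal protein genes had a negative fold change for 77 of 78 (median -0.40, camera adjusted p = 4.14e-10; adjusted p = 0.684 with an estimated correlation). There were 0 edgeR calls over all genes and 0 adjusted over the list alone, 18 lower at an unadjusted p below 0.05 and 1 DESeq2 call. Nuclear genes of oxidative phosphorylation were negative for 51 of 54 (median -0.32, camera adjusted p = 2.16e-07; adjusted p = 0.673 with an estimated correlation). These gave 0 edgeR calls, 12 lower at an unadjusted p below 0.05 and 2 DESeq2 calls. The 13 mRNAs of the mitochondrial genome had a median of 0.61 (camera adjusted p = 0.0177; adjusted p = 0.684 with an estimated correlation). Here edgeR and DESeq2 each called 0, with 4 higher at an unadjusted p below 0.05. Replication-dependent histone genes, many of them near-identical copies, had a median of -0.44 over 49 tested (camera adjusted p = 0.000142; adjusted p = 0.684 with an estimated correlation). The called member was H2AC8 (-3.59, SE 0.593, adjusted p = 0.0165), a low one at 4.79 ± 3.09 CPM in the parental and 0.39 ± 0.154 CPM in the Mettl3 libraries.

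The smaller list calls were cholesterol synthesis (median -0.18, camera adjusted p = 0.00944), epithelial junction genes (-0.18, 0.0157), antigen presentation (-0.30, 0.0255) and extracellular vesicle formation (-0.16, 0.0307) on the lower side. On the higher side they were mRNA decay (0.19, 0.0259), DNA replication and S phase (0.14, 0.0464) and splicing factors (0.16, 0.0468). With an estimated correlation their adjusted p-values were 0.673 for junction, vesicle and decay genes, 0.684 for cholesterol synthesis, antigen presentation and splicing, and 0.843 for S phase. Called members were TM7SF2 of cholesterol synthesis (-0.86, adjusted p = 0.0454) and CLDN3 of the junction list (-1.20, adjusted p = 0.0212), which also holds KRT20. In lists that did not pass, the called members were RBM15 among m6A writers (0.74, adjusted p = 0.0475), UBE2L6 among interferon-stimulated genes (-1.01, adjusted p = 0.0461) and S100A4 among mesenchymal genes (-1.22, adjusted p = 0.0232). In hypoxia and glycolysis they were ALDOC (-3.95, adjusted p = 0.0261) and SLC16A3 (-0.81, adjusted p = 0.0437). ALDOC was low, at 3.2 ± 0.705 CPM in the parental and 0.219 ± 0.191 CPM in the Mettl3 libraries. The 15 lists that did not pass had adjusted p-values from 0.18 to 0.995. They covered m6A writers and readers, the S-adenosylmethionine cycle, microRNA processing, interferon-stimulated genes, NF-kappaB, MYC, p53 and TGF-beta targets, heat shock, hypoxia and glycolysis, mesenchymal genes, and markers of haematopoietic, of fibroblast and endothelial, and of hepatocyte and neural cells. Of those marker lists 5 of 25, 8 of 22 and 6 of 24 genes were expressed enough to be tested.

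Within the m6A machinery, RBM15, a subunit that recruits the writer complex to RNA, rose from 67.7 ± 6.44 to 113 ± 3.91 CPM (log2 fold change 0.74, SE 0.155, adjusted p = 0.0475), a call that ended in all 9 fits with 1 library left out (adjusted p from 0.0548 to 0.222). The other 12 writers, both erasers and the 14 tested readers did not pass; METTL14 stood at 0.39 (adjusted p = 0.309) and FTO at -0.06 (adjusted p = 0.898). The writer list had a positive median (0.07) and a negative mean (-0.34). The sign of the mean came from WTAP and its high count in parental library 1: the mean was 0.04 over the other 12 writers and 0.02 over all 13 without that library. For the readers (median 0.02, mean -0.06) camera's direction was lower. Neither list passed camera, while the writers passed fry's mixed test (adjusted p = 0.00535; 0.187 for the readers). Adjusted over the list alone, 1 writer was higher, RBM15, and 2 were lower, TRMT112 (-0.61, adjusted p = 0.114 over all genes) and RBM15B (-0.52, adjusted p = 0.163), both named after their values were seen.

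The count of 120 was 231 without parental library 1, 58 without parental library 2, 25 without parental library 3, 72 without Alkbh5 library 4, 25 without Mettl3 library 7 and 17 without Mettl3 library 9. DESeq2 called 614 genes, 36.6% of them higher against 24.2% in the edgeR test. Of the 30 named calls, 4, 11 and 17 were lost without parental libraries 1, 2 and 3, 7, 6 and 4 without Alkbh5 libraries 4, 5 and 6, and 17, 10 and 22 without Mettl3 libraries 7, 8 and 9. The calls of MIR30A, ATOH8, SLC44A4, KLHL4, VIL1, SIPA1, KRT20 and REG4 passed in all 9 of these fits. Those of CDX2, HR and CLIC3 passed in 8, NOTUM in 7, SLC7A11-AS1, ASCL2, CLDN3 and H2AC8 in 6, and SLC20A1, APCDD1, DDIT3, JUN, ALDOC and S100A4 in 5. UPP1 passed in 4, CEP152 and SLC16A3 in 3, TM7SF2 in 2, ATF3, NR1D1 and UBE2L6 in 1, and RBM15 in 0. In the fit of only the groups compared, the calls of UPP1, ATF3, DDIT3, CEP152, NR1D1, RBM15, UBE2L6, APCDD1, TM7SF2 and SLC16A3 ended (adjusted p from 0.0645 to 0.11). Those of CEP152, UBE2L6, TM7SF2 and SLC16A3 also ended with the GC correction (0.0555 to 0.0979) and with the GC and length correction (0.0548 to 0.112). Upper-quartile factors ended the calls of UBE2L6 (0.0514) and SLC16A3 (0.0503), and DESeq2 size factors that of NR1D1 (0.054), which ended in 3 further fits (0.0502 to 0.0527).

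Among the lists, intestinal differentiation, WNT targets, YAP targets, ribosomal proteins and oxidative phosphorylation passed in every fit with a library left out or another scaling, filter or correction. The G2/M call ended without Mettl3 library 8 (adjusted p = 0.052), as did those of immediate early genes (0.0837), MAPK and KRAS output (0.0921), antigen presentation (0.0837), mRNA decay (0.0607), S phase (0.835), mitochondrial mRNAs (0.656) and splicing (0.458). Without parental library 1 the calls of histones (0.139), MAPK and KRAS output (0.452), antigen presentation (0.452), mitochondrial mRNAs (0.313), vesicle formation (0.0847), mRNA decay (0.0888) and splicing (0.313) ended. The unfolded protein and ATF4 call ended without Mettl3 library 9 (0.0677), as did those of MAPK and KRAS output (0.137), mRNA decay (0.0924) and splicing (0.137). Without Mettl3 library 7 the calls of junction genes (0.0766), cholesterol synthesis (0.272), vesicle formation (0.182) and S phase (0.182) ended. Parental library 2 decided cholesterol synthesis (0.0678) and S phase (0.654), and parental library 3 vesicle formation (0.0582), mRNA decay (0.0951), S phase (0.634) and splicing (0.121). Leaving out Alkbh5 library 4 or 5, which are in the fit but not in the comparison, ended S phase (0.0527 and 0.0613) and splicing (0.0527 and 0.0755). With the GC correction the junction (0.202), antigen presentation (0.109) and splicing (0.224) calls ended, and with the GC and length correction also those of vesicle formation (0.0858) and mRNA decay (0.106). The S phase call ended with upper-quartile factors (0.0518) and with no filter beyond 1 count (0.134), which also ended mRNA decay (0.07) and splicing (0.142), and splicing ended without mitochondrial genes, RN7SL1 and WTAP (0.052).

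**Figure D3:**
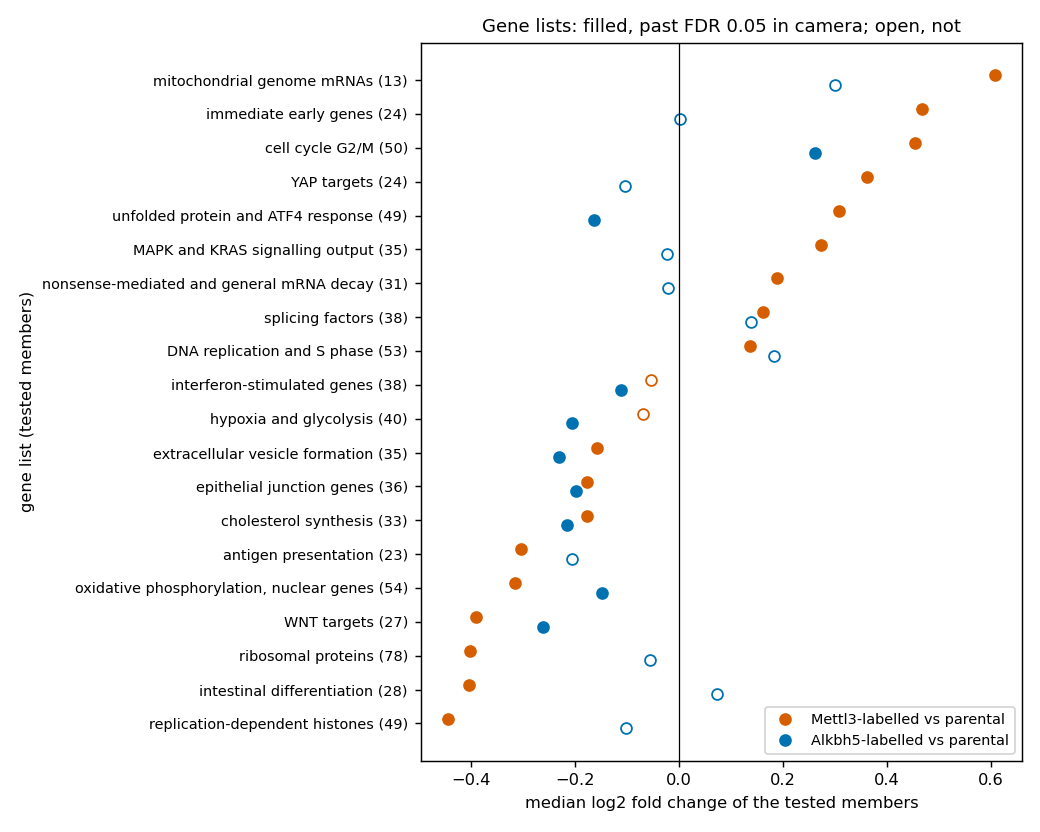
Median log2 fold change against the parental line of the tested members of each gene list that passed camera in either comparison, with the number of tested members in brackets; filled points passed an adjusted p of 0.05 in camera with a preset correlation and open points did not. The unfolded protein and ATF4 list lies at 0.31 in the Mettl3 and -0.16 in the Alkbh5 comparison, while WNT targets lie at -0.39 and -0.26.

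The comparison of the Alkbh5 libraries with the parental line asked which genes differ in the line made to deplete the demethylase. Here too depletion cannot be separated from carrying an shRNA. The edgeR test called 2 genes: ALKBH5 itself, at 146 ± 28.2 CPM in the parental line and 50.3 ± 10.3 CPM in the Alkbh5 libraries (mean ± SD, n = 3 each), and MIR30A, at 22.1 ± 8.4 CPM in the Alkbh5 libraries. An unadjusted p below 0.05 was reached by 1590 of 19731 genes, where 987 would by chance, and DESeq2 called 16.

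MIR30A (chromosome 6, 71403551 to 71403621) encodes the precursor of the microRNA miR-30a and lies inside the annotated span of the non-coding gene LINC00472 (71343427 to 71420745). It had 0, 0 and 3 counts in the parental libraries, 479, 492 and 430 in Alkbh5 libraries 4 to 6, and 693, 253 and 646 in Mettl3 libraries 7 to 9. Scaled for depth, the summed counts were 359 times (95% counting interval 123 to 1740) those of the parental line in the Alkbh5 group and 369 times (126 to 1790) in the Mettl3 group. The edgeR log2 fold changes were 8.51 (SE 0.539, adjusted p = 1.68e-06) and 8.37 (SE 0.54, adjusted p = 2.15e-06), and MIR30A passed in all 9 fits with 1 library left out in both comparisons. LINC00472 itself had 10, 2 and 7 counts in the parental, 6, 3 and 9 in the Alkbh5 and 24, 0 and 4 in the Mettl3 libraries.

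Over gene lists, G2/M cell cycle genes were higher in the Alkbh5 libraries (43 of 50 positive, median 0.26, camera adjusted p = 0.000669; adjusted p = 0.78 with an estimated correlation). Of these edgeR and DESeq2 called 0, and 7 were higher at an unadjusted p below 0.05. WNT targets were lower (21 of 27 negative, median -0.26, camera adjusted p = 0.000938; adjusted p = 0.717 with an estimated correlation). Among WNT targets edgeR called 0 over all genes and 2 adjusted over the list alone, 6 were lower at an unadjusted p below 0.05 and DESeq2 called 1. Extracellular vesicle formation genes were lower (29 of 35 negative, median -0.23, camera adjusted p = 0.00261; adjusted p = 0.717 with an estimated correlation). Of the vesicle genes 0 were called by edgeR or DESeq2 and 2 lower at an unadjusted p below 0.05. The 2 of 35 were a smaller share than that of all tested genes (1590 of 19731). Lower medians passed camera also for oxidative phosphorylation (-0.15, adjusted p = 0.00327), cholesterol synthesis (-0.22, 0.00327), the unfolded protein and ATF4 response (-0.16, 0.00725), interferon-stimulated genes (-0.11, 0.0201), hypoxia and glycolysis (-0.20, 0.0215) and epithelial junction genes (-0.20, 0.0219). With an estimated correlation these gave an adjusted p = 0.717 for junction genes and 0.78 for the other 5. The remaining 24 lists, intestinal differentiation (median 0.07, adjusted p = 0.358) and ribosomal proteins (-0.06, 0.337) among them, had adjusted p-values from 0.0593 to 0.85.

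The WNT and vesicle list calls passed in every fit with a library left out or another scaling, filter or correction. Without parental library 3 the calls of G2/M (0.0508), oxidative phosphorylation (0.0793), interferon-stimulated (0.0706) and junction genes (0.0793) ended. Without parental library 2 those of cholesterol synthesis (0.0764), ATF4 response (0.133), hypoxia (0.0817) and junction genes (0.0853) ended, and without parental library 1 those of interferon-stimulated (0.092) and hypoxia genes (0.0503). Without Alkbh5 library 5 the interferon-stimulated (0.103) and ATF4 response (0.267) calls ended. Without Alkbh5 library 6 those of interferon-stimulated (0.138), hypoxia (0.217), oxidative phosphorylation (0.0926) and junction genes (0.138) ended, and with the GC correction that of junction genes (0.226). The GC and length correction also ended the hypoxia call (0.0644). The interferon-stimulated call ended with the filter of at least 1 CPM in at least 3 libraries (0.0833) and in the fit of only the groups compared (0.0657).

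The direct comparison of the Mettl3 with the Alkbh5 libraries asked where the lines differ from each other. EEF1A2, a translation elongation factor gene whose reads may be shared with its close paralog EEF1A1, was at 9.29 ± 6.87 CPM in the Mettl3 and 109 ± 64.7 CPM in the Alkbh5 libraries, and the chromatin gene BAHCC1 was at 4.36 ± 0.941 and 20.6 ± 5.2 CPM (mean ± SD, n = 3 each). The EEF1A2 call was kept in 3 of 9 fits with 1 library left out (adjusted p from 0.0284 to 0.223), without parental library 3, Alkbh5 library 6 or Mettl3 library 8. It also ended with the GC correction (0.0609), the GC and length correction (0.0673), DESeq2 size factors (0.0638), no filter beyond 1 count (0.352) and the fit of only the groups compared (0.214). VIL1 was lower in the Mettl3 libraries here too, at 5.14 ± 1.23 against 21.3 ± 5.63 CPM, while SLC20A1 was higher, at 475 ± 46.5 against 186 ± 27.2 CPM.

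The edgeR test called 45 genes, 8 higher and 37 lower in the Mettl3 libraries, with 1299 at an unadjusted p below 0.05 against 987 by chance. Named rises were those of BHLHE41, a circadian transcription factor gene (log2 fold change 1.52, SE 0.28, adjusted p = 0.0369), SLC20A1 (1.35, SE 0.219, adjusted p = 0.015), ALKBH5 (1.22, SE 0.192, adjusted p = 0.012) and SIPA1L2 (0.98, SE 0.184, adjusted p = 0.0415). Among called genes with a mean of at least 10 CPM that met the naming rule, the largest falls were those of EEF1A2 (-3.59, SE 0.6, adjusted p = 0.0481), BAHCC1 (-2.25, SE 0.249, adjusted p = 0.00118), VIL1 (-2.06, SE 0.245, adjusted p = 0.00144), STOM (-1.80, SE 0.211, adjusted p = 0.00144) and SIPA1 (-1.60, SE 0.25, adjusted p = 0.0119). MIR30A did not differ detectably between these groups (-0.14, SE 0.292, adjusted p = 0.971).

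All 6 intestinal differentiation genes called against the parental line were also called here (CDX2 at -1.39, adjusted p = 0.0167), of which LGALS4 was kept in 4 of 9 fits with 1 library left out, CDX2 in 6 and the other 4 in all 9, and 10 were lower adjusted over the list alone. Camera called the list lower (median -0.38, adjusted p = 6.16e-08; adjusted p = 0.27 with an estimated correlation). It was the list that passed fry's directional test (adjusted p = 0.0228). The 6 genes had been picked by their fall in the same Mettl3 libraries, so their calls here are not independent of that pick. The unfolded protein and ATF4 response was higher (46 of 49 positive, median 0.42, camera adjusted p = 1.68e-13; adjusted p = 0.364 with an estimated correlation). Of these 0 were called by edgeR over all genes, 12 adjusted over the list alone, 22 at an unadjusted p below 0.05 and 4 called by DESeq2. YAP targets were higher for 23 of 24 (median 0.46, camera adjusted p = 3.24e-10; adjusted p = 0.325 with an estimated correlation). They had 0 edgeR calls over all genes, 6 adjusted over the list alone, 10 at an unadjusted p below 0.05 and 1 DESeq2 call. Ribosomal proteins were lower for 77 of 78 (median -0.37, camera adjusted p = 1.17e-12; adjusted p = 0.683 with an estimated correlation). Here 0 were called by edgeR or DESeq2 and 5 lower at an unadjusted p below 0.05. The 5 of 78 were no larger a share than that of all tested genes (1299 of 19731). Camera also called immediate early genes (median 0.30, adjusted p = 2.88e-06), MAPK and KRAS output (0.30, 1e-04), mRNA decay (0.20, 0.000549), NF-kappaB targets (0.23, 0.00333), p53 targets (0.08, 0.00333) and G2/M genes (0.20, 0.00464) higher. Oxidative phosphorylation (-0.18, 0.000946) and histones (-0.30, 0.00146) were called lower. With an estimated correlation their adjusted p-values ranged from 0.323 for mRNA decay to 0.86 for histones. The other 21 lists, WNT targets (median -0.15, adjusted p = 0.174) and epithelial junction genes (median 0.00, mean -0.21, adjusted p = 0.735) among them, had adjusted p-values from 0.0589 to 0.978.

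The count of 45 was 75 without parental library 1, 23 without Alkbh5 library 4, 13 without Alkbh5 library 5 and 15 without Mettl3 library 9, and DESeq2 called 132. Of the 9 named calls, 6 were lost without Alkbh5 library 5 and 6 without Mettl3 library 9, while BAHCC1, VIL1 and STOM passed in every fit with 1 library left out, SIPA1 in 7 of 9, ALKBH5 in 6, SLC20A1 in 5, EEF1A2 and BHLHE41 in 3 and SIPA1L2 in 2. The histone call ended without Alkbh5 library 4 (0.0723) or 5 (0.578, with the median at 0.01) and without Mettl3 library 7 (0.196) or 9 (0.494). The call of oxidative phosphorylation ended without Alkbh5 library 5 (0.0605) or Mettl3 library 7 (0.535), and that of G2/M without Mettl3 library 8 (0.328, with the median at -0.07).

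Both comparisons with the parental line were set side by side to ask whether the lines changed alike. MIR30A was the gene called in both, higher in both lines. In opposite directions edgeR and DESeq2 each called 0 genes. In edgeR 12 genes of opposite sign reached an unadjusted p below 0.05 in both. Simulated unchanged groups sharing simulated parental libraries gave a mean of 0.875. In the same direction 894 genes reached an unadjusted p below 0.05 in both, against a simulated mean of 191 (166 to 233). Of called genes, edgeR gave 1 in the same direction, where simulated unchanged groups tested with edgeR gave a mean of 0.025. Independent lists of the sizes of edgeR's calls would share 0.00147 higher and 0.00461 lower genes. DESeq2 called 13 genes in the same direction, and no simulation was run with it. Across the 19731 genes, which are not independent replicates, the log2 fold changes correlated at 0.695 (Pearson) and 0.655 (Spearman), where simulated unchanged groups gave a Pearson correlation of 0.517 (0.499 to 0.532). The covariance was 0.226 against 0.084 simulated, a difference of 0.142. The parental libraries were not split between the comparisons, so part of the excess may come from sharing them. Both lines also carry an shRNA and the labels describe no control shRNA group. An effect of carrying an shRNA cannot be told apart from this. The simulations do not hold the deviations of the real parental libraries or the correlation between genes. They therefore do not measure what sharing these libraries would give. The correlation was 0.577 without Alkbh5 library 6 and 0.796 without parental library 3.

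Library composition was compared as shares of all counts. The mitochondrial genome held 8.35% ± 1.48 in the parental, 10.9% ± 1.75 in the Alkbh5 and 11.6% ± 3.28 in the Mettl3 libraries (mean ± SD, n = 3 each), with an exact permutation p of 0.3 for the Mettl3 and 0.2 for the Alkbh5 comparison with the parental line. Ribosomal protein mRNAs held 5.63% ± 0.56, 5.65% ± 1 and 4.12% ± 0.887 in the same order. All 3 Mettl3 libraries lay below all 3 parental ones (exact permutation p of 0.1, the smallest possible). RN7SL1, the RNA of the signal recognition particle, which has near-identical copies and was chosen after its values were seen, held 2.69% ± 0.178, 1.67% ± 0.395 and 1.03% ± 0.238. The exact permutation p was 0.1 for each knockdown group against the parental line and 0.36 after adjustment over all such tests. Fold changes also followed transcript properties. The correlation with GC content was taken across the 11490 genes with a log2 CPM above 2 and a known GC content, which are not independent replicates. The log2 fold change correlated with it at -0.391 in the Mettl3 and -0.362 in the Alkbh5 comparison with the parental line. In the direct comparison the value was -0.179. With gene length, over all genes above the same level, the log2 fold change correlated at 0.245, 0.145 and 0.187 in the same order.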

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

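The tests of small RNA carry-over and of an shRNA cassette for MIR30A, all 3 tests on the intestinal genes, and the tests of mixing and of RNA from other cells for WTAP were chosen only after the result was seen.

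The results below stand out because the effects of the 2 shRNA lines against the parental line differed in the direct edgeR test or, for lists, in camera with its preset correlation. Log2 fold changes of the Mettl3 against the Alkbh5 libraries were -6.01 for KRT20, -3.43 for REG4, -3.34 for H2AC8, -2.06 for VIL1, -1.78 for HR, -1.67 for KLHL4, -1.60 for SIPA1, -1.52 for SLC44A4 and -1.39 for CDX2, and 1.35 for SLC20A1 and 1.22 for ALKBH5. List medians in the same test were 0.455 for YAP targets, 0.418 for the unfolded protein and ATF4 response, 0.297 for immediate early genes, 0.295 for MAPK and KRAS signalling output, 0.231 for NF-kappaB targets, 0.196 for mRNA decay and for G2/M genes, 0.0793 for p53 targets, -0.177 for oxidative phosphorylation, -0.299 for histones, -0.369 for ribosomal proteins and -0.376 for intestinal differentiation. With an estimated correlation none of these 12 list differences passed, at adjusted p-values from 0.27 to 0.86. With 1 library left out, the preset-correlation calls of histones, oxidative phosphorylation and G2/M genes ended in some fits. The G2/M median was -0.0709 without Mettl3 library 8 and the histone median 0.0103 without Alkbh5 library 5. The direct gene calls of KRT20, REG4, VIL1, KLHL4 and SLC44A4 were kept in all 9 such fits. SIPA1 was kept in 7, CDX2 and ALKBH5 in 6, HR and SLC20A1 in 5 and H2AC8 in 4.

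MIR30A stood at 13 to 29.5 CPM in all 6 shRNA libraries and at 0 to 0.123 CPM in the parental ones. Transcription of its locus in the genome stays open. The other 5 genes within 100 kb, planned as its test, changed by -0.237 on the log2 scale in sum (SE 0.231), but 96.4% of their counts were those of OGFRL1, a separate gene 94491 bases away that need not rise with MIR30A. Carry-over of small RNA is argued against by the 40 other tested microRNA genes, whose median was -0.135 and whose highest was 2.13. A candidate explanation is an expressed shRNA cassette built on the miR-30 scaffold, but the levels that would test it (lowest 13 CPM in an shRNA library) are those that prompted it and give it no support. The vector is not in the labels and read positions were not analysed here, so this remains open too.

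The 6 called intestinal differentiation genes had a median log2 fold change of -2.04 in the Mettl3 libraries against the parental line. After the GC and length correction all 6 stayed called with a median of -2.07, though CDX2 shrank from -1.63 to -1.45 and LGALS4 from -1.85 to -1.61. This argues against GC and length bias as the whole cause of the fall of these 6. They had been picked for passing with large falls, so they do not speak for the list. Over all tested members of the list the median shrank from -0.40 to -0.30 with the GC correction and -0.29 with the GC and length correction. Part of the list's shift thus went with these properties. Camera with its preset correlation still called the list lower after the GC and length correction (adjusted p = 0.000701). With 1 library left out, CEACAM5 and LGALS4 were each called in 4 of 9 fits against the parental line. The 6 were picked as lower in these Mettl3 libraries, which the direct comparison uses again. Its result (all 6 lower, median -2.39) is therefore not independent of the pick. Their Alkbh5 fold changes against the parental line ran from -0.25 to 0.77, which argues against a change common to both shRNA lines for these genes. The whole list, fixed beforehand, had a median of 0.07 in the Alkbh5 libraries against the parental line (camera adjusted p = 0.358). Whether loss of METTL3 is the cause cannot be told, because METTL3 mRNA changed by -0.224 with an interval that includes no change and protein was not measured. Drift or selection of a single line per target also stays open and was not tested.

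WTAP took 0.432% of all counts in parental library 1, at 87 times its median elsewhere. Mixing with another library of the series is argued against by the other 8 libraries, none above 57.6 CPM, and RNA from other cells by the absence of companions: 0 other genes of at least 10 CPM stood 8-fold above all other libraries there. Gain of the locus is argued against by ACAT2, TCP1 and SOD2 nearby (SOD2 overlaps WTAP, so its reads are uncertain), whose highest ratio to the other libraries was 1.44, for a second SOD2 entry near 0.5 CPM. RNA or amplified DNA of WTAP from outside the sample, and expression of WTAP alone in that culture, remain open and were not tested.

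Other splits of the 6 libraries of each comparison are too few to give a share under 0.05: the real split was the 1 of 10 with as many calls each time. It gave 120 genes for the Mettl3 libraries against the parental line with at most 0 in another split, 2 for the Alkbh5 libraries with at most 0, and 45 for the direct comparison with at most 1. Every other split mixes both groups on each side, so a difference between groups would add to the spread and lower its calls. The contrast in calls therefore decides nothing.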

How the results depend on the processing

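The fits with a GC correction, with a GC and length correction and without mitochondrial genes, RN7SL1 and WTAP were chosen only after the result was seen; the rest were planned. Gene counts below are for the Mettl3 against the parental, the Alkbh5 against the parental and the Mettl3 against the Alkbh5 libraries, from 120, 2 and 45. They were 624, 21 and 179 with no filter beyond 1 count, 614, 16 and 132 with DESeq2, and 22 and 13 for the first and last at an adjusted p of 0.01. Fitting only the groups compared gave 48 for the first. Leaving out 1 library gave 17 to 231, 1 to 3 and 13 to 75. The share of higher calls in the first comparison was 24.2%, 29.6% with upper-quartile factors, 39.9% with no filter, 36.6% with DESeq2 and 5.88% (without Mettl3 library 9) to 30.3% (without parental library 1) with 1 library left out. In the last it was 17.8%, and 0% (without Alkbh5 library 5) to 25% (without Mettl3 library 7). The other scalings kept 116 and 103 of the 120 calls, the GC correction 90 and the GC and length correction 94, all with the same sign.

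Genes called in the same direction in both shRNA lines went from 1 to 14 with no filter, 13 with DESeq2 and 1 to 2 when leaving out 1 library; those in opposite directions stayed at 0 in all fits. The correlation of fold changes went from 0.695 to 0.617 with no filter and 0.577 to 0.796 when leaving out 1 library. ALKBH5 in the Alkbh5 libraries ranged from -1.69 to -1.38 when leaving out 1 library, with -1.54 and -1.41 in the fits that ended the call (adjusted p over all fits 4.52e-10 to 0.105). METTL3 in the Mettl3 libraries ranged from -0.498 (without parental library 2, edgeR adjusted p = 0.219) to -0.0211 (without parental library 3, adjusted p = 0.98) and passed in no fit.

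Lists called were 18, 9 and 12. With an estimated correlation in camera they were 0, 0 and 0 (1, 0 and 3 at an unadjusted p below 0.05), with fry's directional test 0, 0 and 1, and with its mixed test 14, 1 and 9. Leaving out 1 library gave 10 to 18, 6 to 12 and 12 to 14. The mitochondrial share difference of 3.29 percentage points (Mettl3 minus parental) became 0.641 without the 10 most abundant genes, which include mitochondrial ones, while the ribosomal protein difference of -1.5 became -1.58. The 30, 2 and 9 named calls kept their sign in the fits that gave them a value. WTAP, called in no comparison with the parental line, went from -4.88 and -4.85 to 0.0499 and 0.108 without parental library 1, which alone holds its high count; the lowest values with 1 library left out were -5.45 and -5.41. Of 369 results for called named genes with 1 library left out, 128 lost their call, and in the fit of only the groups compared 11 did; GC correction ended the calls of CEP152, UBE2L6, TM7SF2, SLC16A3 and EEF1A2. Apart from fewer libraries or genes and the other thresholds, the cause was not tested.

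No paired analysis was possible because the count columns carry a running number and not the replicate numbers of the labels, so the planned fit with a replicate block was not run. KRT20 rests on 1 to 6 counts per Mettl3 library. Of simulated 2-fold changes, 27.5% to 36.5% were recovered at these depths, dispersions and group sizes; which of these limits recovery was not tested.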

Other observations

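The lists of the mixed fry test were examined only after the results were seen; it asks whether members change in either direction and does not compare them with other genes. In the Mettl3 libraries against the parental line, 14 lists passed it, against 1 in the Alkbh5 comparison. Lists that camera did not call were among them: mesenchymal genes (adjusted p = 2.82e-05, 23 tested) and TGF-beta targets (adjusted p = 0.0043, 23 tested) held members moving both ways, with 2 mesenchymal genes higher and 4 lower, and 5 TGF-beta targets higher and 1 lower, adjusted over the list alone. The mesenchymal list's median was 0.133 and its mean -0.0852. Among p53 targets (adjusted p = 0.00682, 30 tested), 3 were higher and 1 lower adjusted over the list alone. In the direct comparison of the Mettl3 with the Alkbh5 libraries, 7 were higher adjusted over the list alone. Over all genes edgeR called 0 p53 targets in either comparison. DESeq2 called 3 higher against the parental line and 1 higher in the direct comparison. Hypoxia and glycolysis (adjusted p = 0.0372, 40 tested) had 1 higher and 2 lower adjusted over the list alone. Of the markers of fibroblast and endothelial cells, 8 were tested and 1 was lower adjusted over the list alone (adjusted p = 0.0049; 0.0299 in the direct comparison). The m6A writers, given with the m6A machinery, passed too. In the Alkbh5 comparison the list that passed was that of WNT targets (adjusted p = 0.0203).

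Other members of the intestinal list, chosen after their values were seen, did not pass against the parental line. MUC5AC, a secreted mucin gene, was at 264 ± 23.8 CPM in the parental, 228 ± 51.5 in the Alkbh5 and 281 ± 70.9 in the Mettl3 libraries (mean ± SD, n = 3 each; edgeR adjusted p = 0.861 for Mettl3 against parental). MUC13, a membrane mucin gene, was at 85.9 ± 39.5, 92.3 ± 20.5 and 94.7 ± 20.7 CPM (edgeR adjusted p = 0.819). The liver-intestine cadherin gene CDH17 was at 227 ± 18.6, 233 ± 5.47 and 148 ± 17.4 CPM (log2 fold change -0.61 for Mettl3 against parental, adjusted p = 0.0914).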
